A study of Mus musculus with 6 samples.

How the data were processed

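Total RNA from whole bladders was extracted with a spin-column kit, and biotin-labelled single-stranded DNA made from it was hybridised to an Affymetrix whole-transcript array, per the labels' protocols. The deposited values are log2 signals, 1 per probe set and array, and RMA and Partek are named in the submitters' processing notes without versions or settings. RMA corrects the background, normalizes arrays by quantiles and summarises probes on the log2 scale; whether further steps were applied is not given in the sources used here. Values ran from 1.92 to 14.01 and array medians from 7.60 to 7.84. RMA values are compressed at low signal, so a difference at low signal understates the change in RNA. No detection call was used, and no scanner files were analysed here. The array design and the genome build are not given in the sources used here, so no coordinates are printed.

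The 32025 probe sets carry RefSeq transcript accessions as names. Matched without versions to a RefSeq gene table of mouse assembly GRCm38.p6, used for names only, 25343 had 1 gene symbol, 0 had several and 6682 had none and stayed unnamed (most of these were predicted transcripts). They gave 20263 genes. For the 3289 genes with more than 1 probe set, the one with the highest mean over the 6 arrays stood for the gene. Values of 12 genes were equal on all arrays to those of another gene, and none of these is named. Of 689 list genes 670 were measured.

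The labels give 3 arrays per genotype, each from the bladder of 1 mouse, and the planned fit took 6 independent arrays. All 15 pairs of arrays were compared over genes with a mean log2 signal of at least 8 and over olfactory and vomeronasal receptor genes. A pair of 1 genotype was counted as 1 sample when the SD of its differences was smaller over the expressed genes than over the receptor genes; this held for arrays 2 and 3 of each genotype, which correlated at 0.995 and 0.996 across genes against 0.888 to 0.961 for the other pairs. The array 2 minus array 3 differences were also shared by both genotypes (correlation across expressed genes 0.607, across receptor genes 0.07; genes are not independent replicates). These arrays were averaged, and the planned test was run on 4 samples, 2 against 2. This departs from the planned design. The averaging, the signal limit of 8 and the use of receptor genes were decided after seeing the data, and after limma had been run both ways, with 559 genes past the threshold on 6 arrays and 0 on 4 samples. The fits without both arrays 2 and 3 of a genotype were also added after seeing the data. If all 6 arrays are separate mice, the fit on 4 samples is too strict. All arrays had Y-linked signals typical of males, with Xist at 5.13 to 5.75, so a fit with sex as a covariate did not apply.

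Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, two-sided), knockout minus control, with Benjamini-Hochberg adjustment over all 20263 genes and a threshold of 0.05; differences are on the log2 scale with the moderated SE, and the SD given with a group mean is over the 2 samples. The test had 5.07 degrees of freedom in all. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 between genes, two-sided, adjusted over 32 lists, and again with an estimated correlation, on ranks and with fry (statmod 1.5.0). For each list the genes past 0.05 were counted adjusted over all genes and adjusted over the list alone. The lists were Hedgehog pathway components, Hedgehog targets, BMP ligands, BMP response and inhibitors, Wnt ligands, Wnt targets, superficial, basal and squamous epithelium, proliferation, fibroblasts, smooth muscle, epithelial-mesenchymal transition, T and NK cells, B and plasma cells, macrophages, neutrophils and mast cells, inflammatory cytokines, interferon response, endothelium, neurons and glia, adipocytes, skeletal muscle, male accessory glands, female reproductive tract, blood cells, immediate early and heat shock genes, p53 targets, xenobiotic stress, retinoid signalling, Notch signalling, and FGF, EGF and stromal growth factors. P-values measure the spread between these samples only, and 2 against 2 samples allow 3 splits, so a permutation cannot give a share below 0.333.

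The rule for named genes was also fixed before the data were examined. It took Smo, Gli1, Ptch1, Hhip, Bmp4, Bmp5, Upk1a, Upk1b, Upk2, Upk3a, Krt5, Krt14 and Krt20 always. It took the 10 largest differences in each direction among genes past the threshold with separated arrays or, where fewer than 5 passed, among genes at an unadjusted p under 0.01, said not to have passed. It took up to 4 members with the smallest p of each list described; all 32 lists are described, and of these members those that illustrate a list or reversed are given. Genes outside the rule, which are given beside the uroplakins and gland genes, in the closing section and in the plot of selected genes (Ms4a1, Jchain, Mcpt1, Mcpt2, Chil4, Alox15, Svs2, Svs5, Dpt, Krt6a, Sbp, H2-T22, H2-T23, Upk3bl, Mki67, Top2a and Myh11), were chosen after their values were seen. Predicted gene models, olfactory and vomeronasal receptors and small RNAs were not named. Some genes that the rule took are not reported here, though they stay in the counts and tests.

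The fit was tested on simulated data with the 20263 genes and 200 changed ones, in 20 simulations. From 4 samples it recovered 0.0746% of changes of 1 log2 unit, 1.27% of changes of 2 and 70.0% of changes of 4, with 2.2 false calls on average. When the same 4 samples were given as 6 arrays, with arrays 2 and 3 differing only by noise, it recovered 39.5%, 84.3% and 97.9% but made 386.8 false calls; 6 truly independent samples gave 3.21%, 61.0% and 93.8% with 5.3 false calls. A smooth muscle list lowered by 1 log2 unit was found by camera in 20 of 20 simulations with 0 other lists called, in simulated genes without correlation.

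Alternatives were a spread with intensity trend and robust estimation, leaving out genes below the 30th percentile of mean signal, a further quantile normalization, centring of each array on its median, every probe set by itself, the mean of a gene's probe sets, array weights, the replicate number as a block, each array left out in turn, a plain two-sample test, and other thresholds. Figures were drawn with matplotlib 3.10.9.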

Results

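Gene expression was measured on 6 whole-transcript microarrays of bladders from mice that had drunk water with BBN (N-butyl-N-(4-hydroxybutyl)nitrosamine, a bladder carcinogen) for 2 months. Every mouse carried 1 Gli1 allele with an inserted tamoxifen-dependent Cre recombinase (CreER), which acts only in cells that express the Hedgehog target gene Gli1. The 3 control arrays came from mice with 1 floxed and 1 wild-type allele of Smo, the gene of the membrane protein that passes the Hedgehog signal into the cell. The 3 knockout arrays came from mice with both Smo alleles floxed. Tamoxifen was given for 3 days at 8 weeks of age, before the carcinogen, and bladders were taken at 4 months. The comparison asked how the transcriptome of the carcinogen-exposed bladder differed once Hedgehog response was removed from Gli1-expressing cells, which in the bladder are mainly stromal cells.

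Arrays 2 and 3 of each genotype were nearly the same measurement. Over 10199 expressed genes their log2 differences had an SD of 0.165 between control arrays 2 and 3 and of 0.146 between knockout arrays 2 and 3. Both were below the SD of 0.356 and 0.357 over 1242 olfactory and vomeronasal receptor genes, which are mostly silent in bladder and served as a measure of noise at low signal. Among genes of like mean signal, just under the limit of 8, the margin was smaller. There other genes had 0.219 against 0.276 for receptor genes in the controls, and 0.172 against 0.291 in the knockouts. All 13 other pairs had an SD over expressed genes of 0.590 to 1.12. Control array 1 lay nearer to knockout arrays 2 and 3 (0.590 and 0.598) than to control arrays 2 and 3 (0.766 and 0.784). Arrays 2 and 3 therefore differed less over expressed genes than over receptor genes and were counted as 1 sample, although each is labelled as a separate mouse. This left 2 samples per genotype, called sample 1 and sample 2/3, and n = 2 holds for every mean below. Their number limits the precision. Median log2 signals of the arrays lay between 7.6 and 7.84.

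**Figure D1:**
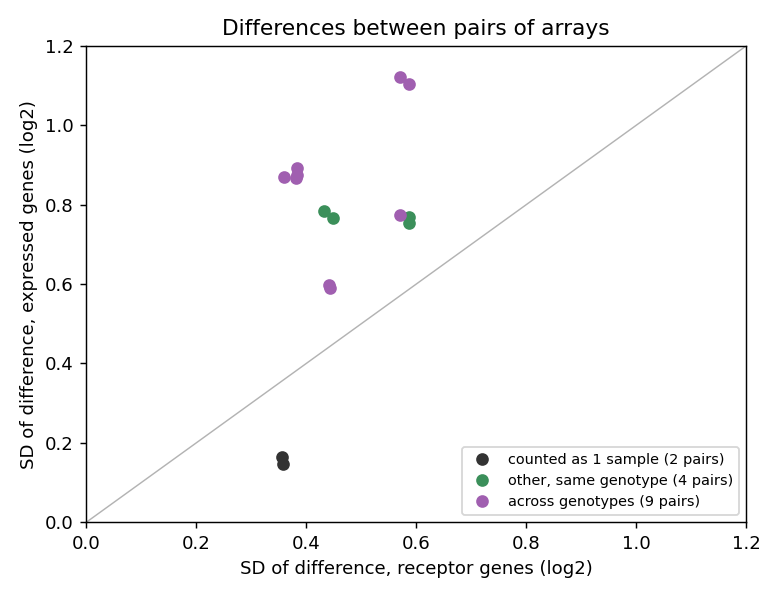
SD of the log2 difference between 2 arrays over expressed genes (vertical axis) against that over receptor genes (horizontal axis); each point is 1 of the 15 pairs of arrays and the line marks equal values. The 2 pairs counted as 1 sample lie below the line, at 0.165 and 0.146, and the 13 others lie above it.

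The targeted gene was measured first. Smo signal was 9.91 in control sample 1, 10.60 in control sample 2/3, 9.88 in knockout sample 1 and 10.38 in knockout sample 2/3. The knockout minus control difference was -0.12 ± 0.37 (log2, SE; limma adjusted p = 0.925), and it turned to 0.13 without knockout array 1 and to 0.22 without control arrays 2 and 3. Deletion is limited to Gli1-expressing cells, control mice also lose 1 allele in those cells, and whether the Smo probes lie in the floxed part is not given in the sources used here. The probe set therefore does not check the genotype labels.

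Among 6 Hedgehog target and BMP ligand genes tested together, Bmp4, Bmp5 and Hhip were lower in the knockout bladders; over all genes none passed. Bmp4 was at 11.14 and 10.87 in controls (samples 1 and 2/3) and averaged 8.54 ± 0.12 (SD) in knockouts, 5.53-fold lower (difference -2.47 ± 0.27, log2, SE). Bmp5 averaged 9.32 ± 0.65 in controls and 6.36 ± 0.49 in knockouts, 7.76-fold lower. Hhip, which encodes a Hedgehog-binding inhibitor and is itself a pathway target, averaged 8.30 ± 0.99 and 6.32 ± 0.29, 3.95-fold lower. Ptch1, the Hedgehog receptor and a classical target, differed by -1.04 ± 0.54 (log2, SE) with overlapping arrays. Gli1 (0.07 ± 0.27) differed by less than its error, and its sign turned with another quantile normalization (-0.0074). Of the 6 genes 3 (Bmp4, Bmp5 and Hhip) passed an adjusted p of 0.05 over the 6 alone, and 0 passed over all genes, where Bmp4 and Bmp5 had an adjusted p of 0.494 and Hhip of 0.552. With all 6 arrays as independent, the planned fit, these 3 genes passed over all genes in limma (adjusted p = 0.0085 for Bmp4, 0.0184 for Bmp5 and 0.0470 for Hhip). Without knockout array 1 the 3 genes became 1.

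The whole BMP ligand list had a median log2 difference of -0.61, with 2 of 11 genes lower and passing in limma when adjusted over the list alone (Bmp4, adjusted p = 0.0026; Bmp5, adjusted p = 0.0058). The list stood below all other genes in camera (adjusted p = 8.7e-04), but with adjusted p = 0.551 with an estimated correlation and 0.268 without knockout array 1. The 2 genes became 1 without knockout array 1 or knockout arrays 2 and 3, 5 without control array 1 and 4 with the replicate number as a block. Bmp3 (-1.28 ± 0.65) and Gdf10 (-0.61 ± 0.35) did not pass. The list of Hedgehog pathway components (median -0.15; camera adjusted p = 8.7e-04; adjusted p = 0.551 with an estimated correlation) held 2 of 17 genes that were lower over the list alone. These were the Hedgehog co-receptor genes Gas1 (-1.57 ± 0.26) and Cdon (-1.52 ± 0.33); the co-receptor gene Boc (-1.21 ± 0.33) and the transcription factor gene Gli2 (-0.69 ± 0.27) missed the threshold. The 2 genes became 0 without knockout array 1, control arrays 2 and 3 or knockout arrays 2 and 3, and 1 without control array 2 or knockout array 2. They also became 1 with an intensity trend, without dim genes, with a further quantile normalization, with centring or with array weights, 3 without control array 1 and 4 with the block. The Hedgehog target list (median -0.43) had 0 of 15 genes past it, and 4 at a list-alone adjusted p of 0.0518, namely Igfbp6 (-1.88 ± 0.39), Foxf2 (-1.05 ± 0.26), Hhip and Foxf1 (-2.54 ± 0.69). Its camera adjusted p was 0.0015, against an adjusted p of 0.551 with an estimated correlation and 0.175 without knockout array 1. The count of 0 became 2 without control arrays 2 and 3 or knockout arrays 2 and 3, 3 without control array 1, 4 without control array 2, control array 3 or knockout array 2, 4 with every probe set by itself and 5 with the block. In the list of BMP response and inhibitor genes (median -0.23; camera adjusted p = 0.0192; adjusted p = 0.551 with an estimated correlation) 0 of 18 genes passed. Its largest differences included the BMP-regulated Smad9 (-1.81 ± 0.41) and Id4 (-1.65 ± 0.45), and the BMP inhibitor genes Chrdl1 (-2.54 ± 0.65) and Fst (1.63 ± 0.47). That call ended with a further quantile normalization (adjusted p = 0.0804), without knockout array 1 (adjusted p = 0.109) and without knockout arrays 2 and 3 (adjusted p = 0.0545). The count became 4 lower and 1 higher without control array 1, 3 lower and 1 higher with the block and 2 lower without control arrays 2 and 3.

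**Figure D2:**
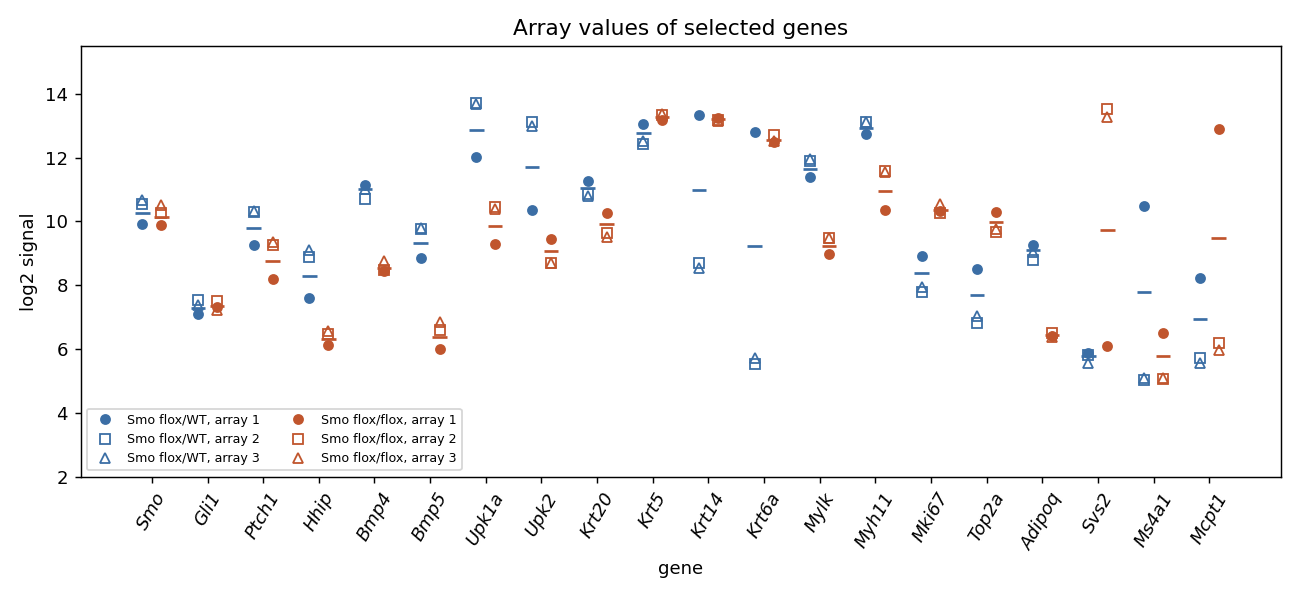
Log2 signal (vertical axis) of 20 genes in each of the 6 arrays, with controls in blue and knockouts in orange; filled circles are array 1, squares and triangles arrays 2 and 3, and short lines the mean of the 2 samples of a genotype. Bmp4 lies at or above 10.7 in the control arrays and at or below 8.76 in the knockout arrays, while Krt14 in control sample 1 (13.34) lies at the level of the knockouts.

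Across all 20263 genes, limma called 0 genes higher and 0 lower at an adjusted p under 0.05 (smallest adjusted p 0.494). At an unadjusted p under 0.05 there were 1412 genes (6.97%, against 5% by chance), 548 higher and 864 lower in the knockouts. By rule the 10 largest differences in each direction were then taken among genes at an unadjusted p under 0.01 with separated arrays; they did not pass the test. All 6 single arrays separated by genotype for 25.3% of all genes. Chance gives 33.3% for 2 averaged samples against 2, which is a looser demand, so the 25.3% cannot be read as below chance. Among the lower genes were Car3 (-4.47 ± 0.44), a carbonic anhydrase of fat and muscle, Cd209f (-3.67 ± 0.61), a lectin of the DC-SIGN family, the small proteoglycan Ogn (-3.51 ± 0.69), the neuropeptide Y receptor Npy1r (-3.28 ± 0.41) and the membrane glycoprotein Gpm6a (-3.22 ± 0.37). Sult1e1 (-3.20 ± 0.80), an estrogen sulfotransferase, Bves (-3.16 ± 0.59), Inmt (-3.09 ± 0.61) and the uroplakin Upk1a (12.02 and 13.70 in controls, 9.29 and 10.43 in knockouts) followed. The higher genes were the antimicrobial lectin Reg3g (4.75 ± 0.33), the annexin Anxa10 (4.34 ± 1.03), the protease inhibitor Spink8 (4.2 ± 0.37), Tnip3 (2.64 ± 0.59), the cornified envelope genes Lce3c (2.65 ± 0.47) and Lce1i (2.40 ± 0.46), and 4 genes of chromosome cohesion, condensation or cell division, Esco2 (2.45 ± 0.55), Cep55 (2.37 ± 0.51), Prc1 (2.34 ± 0.48) and Ncapg (2.33 ± 0.51). With the replicate number as a block 473 genes passed, and without control array 1, which leaves 1 control sample, 735 passed. When all 6 arrays were entered as independent, as the labels have it, 559 genes passed, 187 higher and 372 lower. Among these were 14 proliferation and 4 basal urothelial genes, all higher, and 11 smooth muscle, 9 adipocyte, 3 Hedgehog target and 2 BMP ligand genes, all lower.

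Of 32 gene lists, 20 stood apart from all other genes in camera with the preset correlation, 15 lower and 5 higher in the knockouts. With an estimated correlation 0 of the 20 remained (adjusted p 0.377 to 0.788). The count was 11 without knockout array 1 and 13 without knockout arrays 2 and 3. The median difference over all genes was 0.13 (0.004 without knockout array 1), against which list medians should be read. Fits without array 1 of a genotype, or without both its arrays 2 and 3, leave 1 sample in that genotype. Their degrees of freedom differ. Without knockout array 1 the test had 2.73 in all, against 5.07 in the main fit. Without control array 1 the spread was set almost wholly by the prior. Counts of genes from these fits therefore also follow the degrees of freedom, and not the size of the differences alone.

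Over the mean of the knockout samples, smooth muscle genes formed the group with the largest shift to lower values (median -1.78, 24 of 24 lower). Adjusted over the list alone 17 of 24 were lower, and 0 over all genes. Examples were the creatine kinase Ckb (-2.01 ± 0.28), the myosin light chain kinase Mylk (-2.43 ± 0.34), the intermediate filament protein Synm (-2.03 ± 0.38) and the purinergic receptor P2rx1 (-2.87 ± 0.55). The median was -2.24 in knockout sample 1 and -1.29 in knockout sample 2/3, each against the control mean. In knockout sample 2/3 the adipocyte genes lay slightly lower (median -1.34). Camera gave an adjusted p of 9.4e-26, but adjusted p = 0.551 with an estimated correlation. Without knockout array 1, which leaves 1 knockout sample, the smooth muscle median was -1.29.

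Adipocyte genes were also lower (median -1.42; 17 of 18 lower), and 11 of 18 passed over the list alone, with 0 over all genes. They included Car3, the hormones Adipoq (-2.66 ± 0.27) and Retn (-1.96 ± 0.38), and the lipid droplet protein Plin4 (-1.85 ± 0.32). Both knockout samples had nearly equal medians, -1.33 and -1.34. The adjusted p was 3.5e-16 in camera and 0.0270 in the directional fry test, which sets a list against no change and not against other genes. Camera gave adjusted p = 0.377 with an estimated correlation, and 0.0339 when the 6 arrays were entered as independent. The 11 genes became 2 without knockout array 1, 7 without control array 1 and 4 without knockout arrays 2 and 3.

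The other stromal lists differed less, and few or none of their genes passed. Fibroblast and matrix genes had a median of -0.49 with 0 of 29 past the list-alone threshold; Fbln1 (-2.10 ± 0.57), Cd34 (-1.64 ± 0.46) and Col6a1 (-1.01 ± 0.29) were among the genes with lower means. Their camera adjusted p of 3.4e-05 became adjusted p = 0.656 with an estimated correlation and 0.709 without knockout array 1; the median was -1.06 in knockout sample 1 and -0.02 in knockout sample 2/3. The count of 0 became 16 lower and 1 higher without knockout arrays 2 and 3, 3 lower and 1 higher without control array 1, 3 lower without control arrays 2 and 3, and 5 lower and 1 higher with the replicate number as a block. Endothelial genes had a median of -0.51 and 0 of 21 passed (Prox1, -0.88 ± 0.43; Kdr, -0.94 ± 0.48; Sox18, -0.53 ± 0.28). The camera adjusted p of 1.7e-04 became adjusted p = 0.651 with an estimated correlation, 0.314 without knockout array 1 and 0.174 without control array 1. In the list of neurons and glia (median -0.14; camera adjusted p = 0.0040; adjusted p = 0.551 with an estimated correlation; 0.0662 without knockout array 1) 2 of 20 genes were lower over the list alone, Cdh19 (-2.54 ± 0.32), a cadherin of Schwann cells, and Gfra3 (-1.38 ± 0.28), a receptor of artemin. The sodium channel gene Scn7a (-2.72 ± 0.83) did not pass. The 2 genes became 0 without knockout array 1 or without dim genes, 1 without knockout array 2 or with an intensity trend, 3 without control array 1 or control array 2 and 4 with the block.

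Secreted factors and their targets differed gene by gene. Among 17 Wnt ligands 1, Wnt2b (-1.74 ± 0.27), was lower over the list alone, while Wnt2 (-1.51 ± 0.50), Wnt5a (-1.39 ± 0.59) and Wnt4 (0.79 ± 0.36) did not pass; the list median was 0.30 (camera adjusted p = 0.496), and the 1 gene became 0 without knockout array 1 or knockout arrays 2 and 3, 2 without control arrays 2 and 3 and 3 with the block. Wnt target genes had a median of -0.28 and 0 of 15 past the threshold, led by the feedback inhibitor genes Nkd1 (-1.58 ± 0.39) and Nkd2 (-1.66 ± 0.55). Their camera adjusted p was 0.0240, with adjusted p = 0.551 with an estimated correlation, 0.176 without knockout array 1, 0.0624 without control array 1, 0.0704 without control arrays 2 and 3, 0.0545 without knockout arrays 2 and 3 and 0.0552 with a further quantile normalization. The list of FGF, EGF and stromal growth factors did not shift (median 0.06; camera adjusted p = 0.390; 0 of 24 past the threshold), with Fgf7 (-2.25 ± 0.42) and Fgf1 (-0.98 ± 0.27) lower and Vegfa (1.12 ± 0.26) higher at limma unadjusted p values of 0.0030, 0.0147 and 0.0073. Without control arrays 2 and 3 its median was -0.32 and it stood below other genes (adjusted p = 0.0347).

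In the urothelium, the epithelium that lines the bladder, superficial differentiation genes had a median of -0.65 with 0 of 28 past the list-alone threshold. The uroplakin genes, which encode the plaque proteins of the superficial cells, did not pass. Their differences were -2.63 ± 0.92 for Upk2, -2.49 ± 0.60 for Upk3b, -2.23 ± 1.33 for Upk3a, whose arrays overlapped, and -1.15 ± 0.50 for Upk1b (log2, SE). The uroplakin-like Upk3bl was at 1.42 ± 1.00. Krt20, a keratin of superficial cells, was at -1.12 ± 0.36. Upk1a was among the 10 largest lower differences of the genes at a limma unadjusted p under 0.01 with separated arrays. Elf3 was at 1.12 ± 0.37. Control sample 1 lay below control sample 2/3 in this list by a median of 1.31. Against control sample 1 alone the knockouts had medians of -0.35 and 0.09. Its Upk3a signal (7.77) was within the range of the knockouts (7.86 and 7.36) against 11.91 in control sample 2/3. The camera adjusted p of 0.0033 became adjusted p = 0.572 with an estimated correlation, 0.341 without knockout array 1 and 0.0936 without control arrays 2 and 3. Without control array 1 the count of 0 became 12 lower and 2 higher, and with the replicate number as a block 14 lower and 1 higher.

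Basal urothelial genes had a median of 1.14, with 17 of 19 means higher in the knockouts, and 0 of 19 passed over the list alone or over all genes. The largest differences relative to their errors were those of the laminin chains and integrins that anchor basal cells to the basement membrane, Itga3 (1.35 ± 0.30), Lamb3 (1.14 ± 0.28), Lama3 (1.03 ± 0.26) and Itga6 (1.10 ± 0.32). Against control sample 1 alone the list medians were 0.13 in knockout sample 1 and 0.68 in knockout sample 2/3, and against control sample 2/3 alone 1.29 and 1.59. Krt5 differed by 0.51 ± 0.31. Krt14 had 13.34 in control sample 1, 8.61 in control sample 2/3, 13.24 in knockout sample 1 and 13.16 in knockout sample 2/3, so its difference of 2.23 rested on control sample 2/3 and was -0.14 without control arrays 2 and 3. The camera adjusted p of 3.2e-06 became adjusted p = 0.572 with an estimated correlation and 0.0545 without knockout arrays 2 and 3; over the list alone 7 genes were higher without control array 1, 3 with a further quantile normalization and 12 with the block.

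Squamous and cornified epithelium genes, the program of stratified skin-like epithelium, had a median of 1.75 with 26 of 28 higher and 0 past the list-alone threshold. Lce3c (2.65 ± 0.47), Dsc1 (1.78 ± 0.37), Lor (1.35 ± 0.33) and Krt1 (2.92 ± 0.83) led it. This list was split between the controls: control sample 1 lay above control sample 2/3 by a median of 3.31, and against control sample 1 alone the knockouts had medians of 0.04 and -0.19. Camera gave an adjusted p of 9.6e-06, with adjusted p = 0.656 with an estimated correlation, 0.361 without control arrays 2 and 3 (median -0.16) and 0.0733 without knockout arrays 2 and 3. Over the list alone 24 genes were higher and 1 lower without control array 1, 19 higher and 1 lower with the replicate number as a block, 1 higher without control arrays 2 and 3, 1 without control array 2, and 2 with an intensity trend or with centring.

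Proliferation genes were higher in the knockouts without exception (median 1.70; 34 of 34), and 20 of 34 passed over the list alone, with 0 over all genes. They included the kinetochore motor Cenpe (2.08 ± 0.35), the transcription factor Mybl2 (1.67 ± 0.31), Hmmr (2.02 ± 0.41) and the spindle midzone protein Prc1 (2.34 ± 0.48). Control sample 1 lay above control sample 2/3 by a median of 1.17, and the knockout samples lay above control sample 1 by medians of 1.08 and 1.09. Against the control mean the medians were 1.71 in knockout sample 1 and 1.66 in knockout sample 2/3. Camera gave an adjusted p of 1.6e-22 and adjusted p = 0.551 with an estimated correlation. The 20 genes became 0 without knockout array 1, 0 without control arrays 2 and 3, 0 without knockout arrays 2 and 3, 0 with array weights, 30 without control array 1 and 32 with the replicate number as a block.

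Genes of epithelial-mesenchymal transition and invasion did not shift as a list (median 0.27; camera adjusted p = 0.464, on the lower side of all other genes). Zeb1 (-1.47 ± 0.27) and Zeb2 (-1.83 ± 0.34), transcription factors that are high in mesenchymal cells, were the 2 of 24 genes that were lower over the list alone. Spp1 (3.33 ± 0.88) and the protease gene Mmp7 (4.07 ± 1.44) were higher without passing, with Mmp7 at 10.20 in control sample 1, 5.68 in control sample 2/3 and 11.90 and 12.14 in the knockouts. The list median turned to -0.05 without knockout array 1 and to -0.16 without control arrays 2 and 3 (adjusted p = 0.0062), and the 2 genes became 0 without knockout array 1, without knockout arrays 2 and 3 or with centring. In turn 2 genes were higher with the block or without control arrays 2 and 3. Without control array 1 the list stood above other genes (median 0.45, adjusted p = 8.0e-05), with 7 genes higher.

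Immune genes followed single samples more than genotype. B and plasma cell genes (median -0.80; camera adjusted p = 0.0015; adjusted p = 0.763 with an estimated correlation), T and NK cell genes (-0.35; 0.0018; adjusted p = 0.788 with an estimated correlation) and macrophage and dendritic cell genes (-0.39; 0.0084; adjusted p = 0.788 with an estimated correlation) had 0 of 15, 0 of 26 and 0 of 26 genes past the list-alone threshold. Control sample 1 exceeded control sample 2/3 in them by medians of 2.53, 1.23 and 1.61, and without control array 1 the medians of the knockout difference were 0.41, 0.20 and 0.29. The B and plasma cell list then stood above other genes (adjusted p = 0.0364). The calls of the T and NK cell list and the macrophage list then ended (adjusted p = 0.411 and 0.0742), as they did without dim genes (0.0578 and 0.0520). The macrophage call also ended without knockout array 1 (0.140), and without knockout arrays 2 and 3 those of all 3 lists did (0.0545, 0.141 and 0.0545). Without control arrays 2 and 3, 13, 7 and 8 genes were lower over the list alone. Among these lists' leading members, none past a threshold, were the plasma cell gene Mzb1 (-1.62 ± 1.36), which turned to 0.49 without control array 1, the plasma cell receptor Tnfrsf17 (-1.19 ± 0.84; 0.077 without it), the cytotoxic granule gene Nkg7 (-1.41 ± 0.80) and Cd4 (-0.90 ± 0.68; 0.10 without it). Within the macrophage list H2-Eb1 (1.87 ± 0.45) was higher, and Lyz1 (-1.41 ± 0.43), Clec10a (-1.19 ± 0.59) and Mrc1 (-0.76 ± 0.48) lower, without passing.

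Inflammatory cytokine genes had a median of 0.61 (camera adjusted p = 0.0240; adjusted p = 0.788 with an estimated correlation; 0 of 28 past the threshold), with Lif (1.14 ± 0.28), Lcn2 (2.12 ± 0.59), Il33 (1.51 ± 0.76) and Csf2 (0.90 ± 0.50) as leading members. The call ended with array weights (0.0618), without knockout array 1 (0.393) and without knockout arrays 2 and 3 (0.116), and without control arrays 2 and 3 the list stood below other genes (median -0.04, adjusted p = 0.0202); over the list alone 14 genes were higher without control array 1 and 5 with the replicate number as a block. The interferon response list (median 0.77; camera adjusted p = 0.0777; 0 of 30 past the threshold) had a median of 1.56 in knockout sample 1 and -0.05 in knockout sample 2/3; Oas2 (2.40 ± 0.67), Ifi44 (2.06 ± 0.67) and Oas3 (1.70 ± 0.63) were higher and Gbp5 (-1.88 ± 0.32) lower without passing. Its median was -0.05 without knockout array 1 and -0.02 without control arrays 2 and 3, and it passed without control array 3 (0.0308), knockout array 2 (0.0345), knockout arrays 2 and 3 (0.0300) or control array 1 (7.7e-12), without dim genes (0.0491) and with the block (3.8e-05; 13 genes higher and 1 lower over the list alone). Neutrophil and mast cell genes (median 0.44; camera adjusted p = 0.333) had 0 of 18 past the threshold; the median turned to -0.24 without knockout array 1 and -0.09 without control arrays 2 and 3. The list stood above other genes without control array 1 (median 1.14, adjusted p = 1.2e-08) and with the block (0.0301). The mast cell genes Ms4a2 (0.89 ± 0.75) and Tpsab1 (1.11 ± 0.94) turned to -0.23 and -0.32 without knockout array 1, and the neutrophil granule gene Ltf (2.78 ± 1.96) turned to -0.29 without control arrays 2 and 3.

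Genes of the male accessory glands had a median of 1.53 (camera adjusted p = 0.0054; adjusted p = 0.575 with an estimated correlation; 0 of 18 past the threshold), at 2.98 in knockout sample 2/3 against 0.17 in knockout sample 1. Pbsn was at 3.78 and 3.33 in the controls, 4.03 in knockout sample 1 and 10.45 in knockout sample 2/3, and Tgm4 at 5.91, 5.80, 6.25 and 12.05 in the same order. Crisp1 was at 10.52, 4.13, 10.51 and 11.54, and Sbp at 10.97, 5.73, 5.20 and 10.08. Pax2, whose difference of 0.97 ± 0.52 came mostly from knockout sample 1, was at 7.17, 7.13, 8.85 and 7.40. Without knockout arrays 2 and 3 the adjusted p was 0.785; over the list alone 9 genes were higher without knockout array 1, 12 without control array 1, 7 (and 1 lower) without control arrays 2 and 3 and 5 with the block. Every value of knockout sample 2/3 given above was measured in RNA that held such transcripts. Control sample 1 held Crisp1 and Sbp, and knockout sample 1 held Crisp1 at the same level as control sample 1.

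Xenobiotic and oxidative stress genes (median -0.06; 0 of 25 past the threshold) stood below other genes in camera (adjusted p = 0.0240; adjusted p = 0.735 with an estimated correlation), which ended without control array 1 (0.873; median 0.08), without knockout array 1 (0.709; median 0.03), without dim genes (0.0793), with a further quantile normalization (0.0671) and with every probe set by itself (0.0738). Its leading members were the cytochrome P450 gene Cyp1a1 (-2.77 ± 0.86) and the glutathione transferase gene Gstm1 (-1.87 ± 0.67). With all samples the remaining lists did not stand apart and had 0 genes past the list-alone threshold. Their medians and camera adjusted p values were 0.35 and 0.154 for skeletal muscle, 0.28 and 0.176 for immediate early and heat shock genes, 0.16 and 0.333 for p53 targets, 0.29 and 0.766 for the female reproductive tract, 0.14 and 0.846 for Notch signalling, 0.11 and 0.464 for retinoid signalling and -0.08 and 0.464 for blood cells. The blood cell list had a mean of 0.01 against its negative median, and the retinoid and growth factor lists had positive medians but lay on the lower side in camera. The blood cell median turned to 0.31 without control array 1 (adjusted p = 0.0112) and was -1.26 without control arrays 2 and 3 (3.0e-05). The retinoid median turned to -0.30 without control arrays 2 and 3 (0.0196) and -0.02 without knockout arrays 2 and 3 (0.0449). Without knockout array 1 the skeletal muscle list (0.0040) and the p53 target list (0.0289) stood above other genes, as did the skeletal muscle list without control arrays 2 and 3 (0.0464) and the immediate early list with every probe set by itself (0.0400). Leading members, none past a threshold, were the platelet chemokine Pf4 (-1.71 ± 0.53), the retinol carrier Rbp4 (-1.69 ± 0.44), the Notch target Hey2 (-0.89 ± 0.29), the stress transcription factor Atf3 (1.27 ± 0.49), the p53 target Pmaip1 (0.87 ± 0.37) and the progesterone receptor Pgr (-0.61 ± 0.37). In the skeletal muscle list Ckm (-1.72 ± 0.41), Acta1 (-1.74 ± 0.53) and Eno3 (-1.63 ± 0.58) were lower and Myl1 (1.39 ± 0.46) higher without passing.

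**Figure D3:**
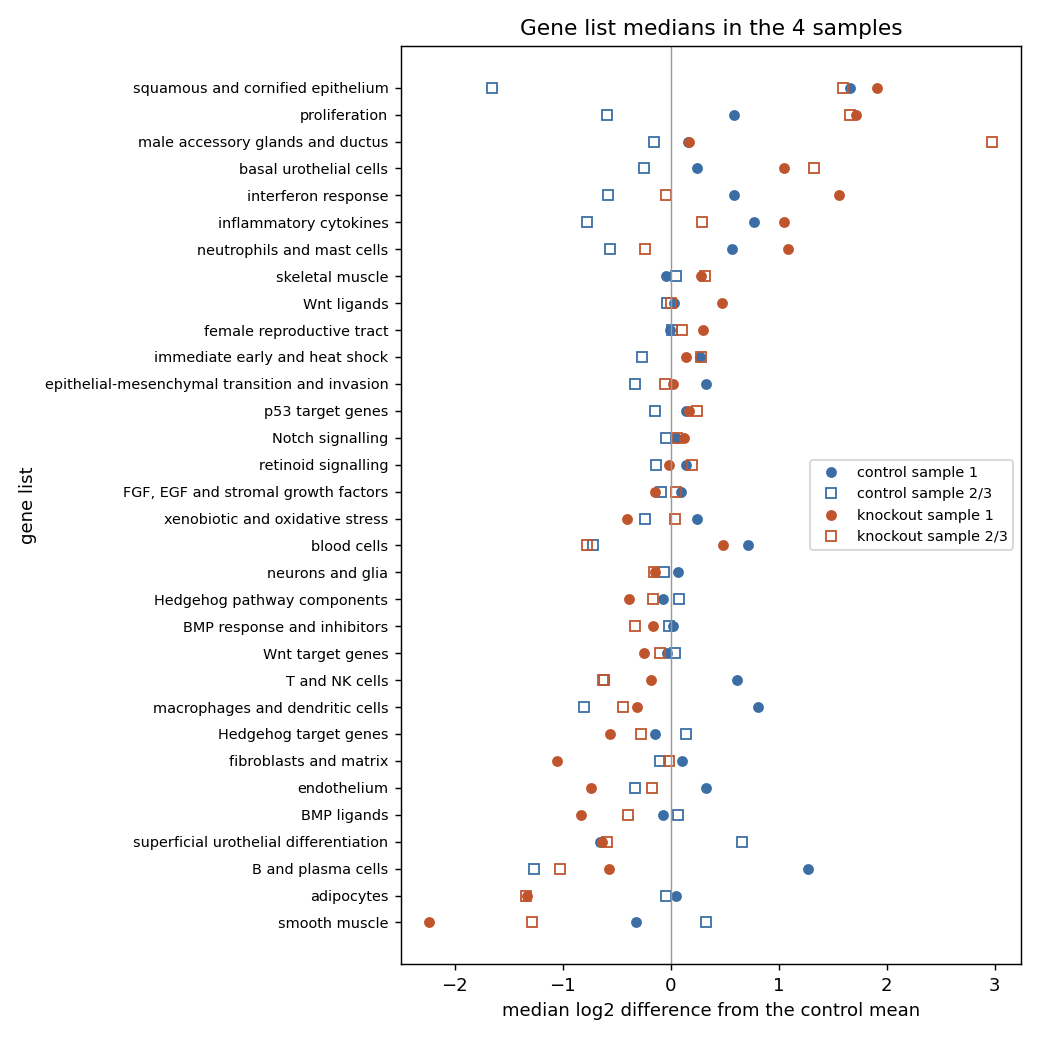
Median over each list's genes of the log2 difference from the control mean (horizontal axis) for 32 gene lists (vertical axis), with control samples in blue and knockout samples in orange; filled circles are sample 1 and open squares sample 2/3. Smooth muscle lies at -2.24 and -1.29 and adipocytes at -1.33 and -1.34 in the knockouts, while the squamous list in control sample 1 lies with the knockouts.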

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

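The fit on 6 independent arrays was the planned one. The averaging to 4 samples was chosen after seeing the data, as were the block on 6 arrays and the fits without both arrays 2 and 3 of a genotype; the other alternatives were planned before the data were examined and run here on the 4 samples. The count of genes changed between genotypes stayed at 0 with the intensity trend, without dim genes, with quantile normalization, centring, every probe set, mean probe sets, array weights, the plain two-sample test (947 genes at an unadjusted p under 0.05) and an adjusted p under 0.1. It was 991 at an unadjusted p under 0.05 with a log2 difference of at least 1 (351 higher, 640 lower), 559 with 6 arrays as independent, and 138 without both control arrays 2 and 3. With the replicate number as a block it was 473 on the 4 samples (157 higher, 316 lower) and 677 on the 6 arrays, and 264 genes were shared by the block on 4 samples and the 6 independent arrays. Deviations of same-numbered arrays correlated at 0.159, 0.148 and 0.227 across genes, all above 0.1, but with arrays 2 and 3 counted as 1 sample there is 1 independent value, 0.159, and the numbers were not taken to pair the mice. This was settled after the counts of the fits without a block had been seen. Other values leave a shared effect of the number open. The array 2 minus array 3 differences were shared by both genotypes (correlation 0.607 across expressed genes). Samples 1 against samples 2/3 gave 935 genes at a limma unadjusted p under 0.05. Control sample 1 with knockout sample 2/3 against the others gave 301. If the numbers do pair the mice, the values with the block hold. Leaving out each array gave 0 to 735 genes; the 735 arise without control array 1, where 1 residual degree of freedom is left, the spread is set almost wholly by the prior, and the lone control is assumed to vary like the knockouts.

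The 20 lists became 0 with an estimated correlation, 13 without both knockout arrays 2 and 3, and 11 to 21 with each array left out. In fry, which tests each list against no change and not against other genes, 1 list passed in the directional and 1 in the mixed form (adipocytes in both). With camera on ranks the BMP response call ended (adjusted p = 0.0825), and the interferon and skeletal muscle lists passed (0.0491 for both). With 6 independent arrays the calls of B and plasma cells, macrophages and xenobiotic stress ended (camera adjusted p = 0.0605, 0.208 and 0.250), while adipocytes passed with an estimated correlation too (0.0339), and with the block on 6 arrays those of macrophages (0.152) and xenobiotic stress (0.197) ended and the interferon list passed (0.0053). The 17 smooth muscle genes past the list-alone threshold ranged over 0 to 22 with an array left out, the 11 adipocyte genes over 2 to 11 (4 without both knockout arrays 2 and 3), and the 3 of 6 Hedgehog and BMP genes over 1 to 4. The 20 proliferation genes ranged over 0 to 30. They became 0 with array weights, 32 and 34 with the block on 4 samples and on 6 arrays, 33 with 6 independent arrays, and 0 without both control or both knockout arrays 2 and 3. Array weights were equal within a genotype (1.66 for controls, 0.601 for knockouts), so they could not separate its samples.

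The Smo difference ranged from -0.47 to 0.13 with an array left out and was 0.22 without both control arrays 2 and 3. Gli1 turned to -0.0074 with quantile normalization and ranged from -0.12 to 0.14. Krt14 turned to -0.14 without both control arrays 2 and 3. Without both control arrays 2 and 3, Ltf also turned to -0.29 and Ppbp to -0.36. With an array left out, Cd4 ranged from -0.93 to 0.10, Tnfrsf17 from -1.35 to 0.077, Mzb1 from -1.94 to 0.49, Derl3 from -1.02 to 0.25, Alas2 from -1.10 to 0.14, Ms4a2 from -0.23 to 0.95, Tpsab1 from -0.32 to 1.31, Hoxa13 from -2.27 to 0.014 and Slc4a1 from -0.045 to 0.31, the first 5 turning without control array 1 and the last 4 without knockout array 1. The other genes that the naming rule took and that are named in the comparisons kept their direction in all alternatives run. Sbp and Upk3bl lie outside that rule and were followed only on the 6 independent arrays, where Sbp turned from -0.71 to 0.98 and Upk3bl went from 1.42 to 2.04. Apart from fewer samples, the cause was not tested. Sex as a covariate was not run, since all arrays came from males.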

Other observations

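All tests in this part were chosen after the results they bear on were seen, and the genes named here for single samples were chosen after their values were seen. In control sample 1, 45 genes lay at least 2 log2 units above the 3 other samples. They included 7 of 15 B and plasma cell genes and 3 of 26 T and NK cell genes (one-sided exact hypergeometric, adjusted p = 3.3e-14 and 4.1e-04 over 32 lists, over genes that are not independent). Ms4a1 (the B cell antigen CD20) was at 10.50 against 5.06, 6.52 and 5.08 in control sample 2/3, knockout sample 1 and knockout sample 2/3. Jchain, which joins secreted antibodies, was at 12.28 against 5.82, 9.41 and 8.61. The T cell gene Cd3g was at 9.54 against 6.18, 6.50 and 5.79.

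In knockout sample 1, 62 genes lay at least 2 log2 units above the 3 other samples, and no list was over-represented among them (at most 1 gene of a list). They included small RNAs, which by rule were not named. Of these 62, the mast cell protease gene Mcpt1 was at 12.89 against 8.23, 5.64 and 6.08 in control sample 1, control sample 2/3 and knockout sample 2/3, and its relative Mcpt2 at 12.77 against 8.58, 4.54 and 4.65. The chitinase-like gene Chil4 was at 13.29 against 6.99, 3.76 and 4.14, and the lipoxygenase gene Alox15 at 12.09 against 8.89, 6.92 and 7.19. Knockout array 1 also had the narrowest spread of signals over all probe sets (SD 1.98 against 2.08 to 2.15 in the other arrays). Its lower quartile was the highest (6.44 against 6.04 to 6.17). Whether these 62 genes reflect the mouse or the array was not tested.

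With 6 arrays there are 10 splits 3 against 3 and with 4 samples 3 splits, too few for a share under 0.05. Of the 10 splits 1, the real one, gave as many as 559 genes past the threshold, and the highest other gave 9. Only the real split and the one with 9 genes kept arrays 2 and 3 of each genotype on the same side. The others put nearly the same measurement on both sides and gave 0 genes, so they are no fair comparison for the real split. Of the 3 splits of the 4 samples 1, the real one, gave as many as 1412 genes at an unadjusted p under 0.05, and the highest other, samples 1 against samples 2/3, gave 935. The remaining split gave 301.

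Knockout sample 2/3 held transcripts of male accessory glands. Of the genes of that list, Sbp and Crisp1 were also high in control sample 1, and Crisp1 in knockout sample 1. Sbp was at 10.97 in control sample 1 and 10.08 in knockout sample 2/3 against 5.73 and 5.20 in control sample 2/3 and knockout sample 1. Crisp1 of the male accessory gland list was at 10.52, 11.54, 4.13 and 10.51 in the same order, so only control sample 2/3 was low in it. Krt6a and Ltf, outside that list, were also low only there, so Crisp1 alone does not show gland tissue in knockout sample 1. Of 18 genes of that list 10 lay at least 2 log2 units above every other array, where 42 of 20263 genes did (one-sided exact hypergeometric p = 2.0e-23, over genes that are not independent); Svs2 was at 13.51 and 13.27 in knockout arrays 2 and 3 against at most 6.09 elsewhere, and Svs5 at 12.96 and 12.91 against at most 6.56. An effect of the genotype in both samples is argued against for the 10 genes that lay 2 log2 units above the control arrays in knockout arrays 2 and 3, chosen without regard to knockout sample 1: there their highest excess over the controls was 0.34 log2 units. Pax2 of the list, at most 7.24 in the controls and 8.85 in knockout sample 1, was not among them and stays unexplained. Tissue of these glands taken with the bladder may be the source of the 10, and an effect of the genotype in that mouse alone stays open.

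Lower smooth muscle genes, Bmp4 and Bmp5 were seen in both knockout samples. Smooth muscle genes lay below fibroblast and matrix genes by a median difference of -1.28, with -1.18 in knockout sample 1 and -1.27 in sample 2/3. In neither sample did these 2 lists fall alike. Permutation p values were 1e-05 (the smallest the 100000 resamples can give), 0.00025 and 1e-05. They permuted genes and not mice, and took genes as independent. The estimated correlation was 0.76 between smooth muscle genes and 0.53 between fibroblast and matrix genes. The smooth muscle list was also picked after its shift had been seen. These p values therefore cannot decide whether the share of all stroma was lower alike. Dilution by gland tissue is argued against for knockout sample 1 only, where the smooth muscle median was -2.24. The raised gland genes stayed near the controls there, though Crisp1 was at 10.51 in it, as in control sample 1 (10.52). For the median of -1.29 in knockout sample 2/3 such dilution stays open, since the values of another sample cannot decide it. A loss of fibroblasts or of muscle as the reason for the lower Bmp4 and Bmp5 cannot be told apart. Both lay below all 29 fibroblast and matrix genes in the mean and in knockout sample 2/3. In knockout sample 1, however, 6.9% of these genes, Dpt (-2.96) and Fbln1 (-2.92), were as low as Bmp4 (-2.55). Of the smooth muscle genes 12.5% were as low as Bmp4 and 4.17% as low as Bmp5 in the mean. These shares were 37.5% and 8.33% in knockout sample 1, and 4.17% and 0% in knockout sample 2/3. An effect of the genotype on BMP transcription itself stays open and was not tested, since no values per cell type exist in these data.

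The squamous list in control sample 1 was at the level of the knockouts by its median (knockouts minus control sample 1, 0.04 and -0.19), but not in every gene. Krt6a was at 12.80 in control sample 1, 12.50 and 12.60 in the knockouts and 5.64 in control sample 2/3. Krt1 was lower in control sample 1 (9.27) than in the knockouts (10.61 and 11.36), as were Lce3c, Dsc1 and Lor. Over all expressed genes control array 1 lay nearer to knockout arrays 2 and 3 (SD 0.590 and 0.598) than to control arrays 2 and 3 (0.766 and 0.784). It lay at 0.773 from knockout array 1. A knockout labelled as control cannot be told apart. Of the 6 Hedgehog target and BMP ligand genes 3 were higher in control sample 1 than in every knockout array (Bmp4, Bmp5 and Hhip, by 2.38, 2.02 and 1.02). Both knockouts also lay below it in adipocyte genes (medians -1.42 and -1.18) and smooth muscle genes (-1.82 and -0.94). All of these values go against such an error. Ptch1 (-0.08), Gli1 (-0.41, at a signal below the array medians) and the distances over all expressed genes do not. These genes and lists were called with the labels in question, and 2 knockouts do not show how far knockouts vary. A strain difference of the mouse behind control sample 2/3 cannot be told apart: 2 of 38 histocompatibility genes, H2-T22 and H2-T23, were among the 147 genes at least 2 log2 units lower in that sample than in the 3 others, but so were 18 of 28 squamous genes, and such genes also respond to inflammation.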
